A study of Mus musculus with 13 samples.

How the data were processed

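RNA of 3 adrenal glands and of 10 neuroblastomas from transgenic mice on a C57BL/6 background was measured on Affymetrix mouse arrays. The transgenes are expressed in the neural crest, the animals were watched until a tumour could be felt, and RNA was prepared with a QIAGEN kit and labelled with biotin by the Affymetrix protocol. The deposited values are RMA summaries by the authors, background-corrected, quantile-normalized and on the log2 scale, made in Partek according to the submitters' processing notes, which state no versions. The values run from 2.04 to 14.5, and the sorted values of the 13 arrays differ by at most 0.129. Detection calls were not used here, and whether all arrays went through RMA in 1 session is not stated.

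The table holds 45101 probe sets, of which 64 are controls, 35890 carry a gene name and 9211 carry none. Probe sets with exactly 1 symbol (34958) were used and those with several (932) were left out. Symbols were looked up in a RefSeq table of mouse assembly GRCm38.p6, which matched 34754 probe sets and changed 0 symbols. Each gene was represented by its probe set with the highest mean over the 13 arrays, which gave 18193 genes, and no filter on dim genes was applied.

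Groups were taken from the labels. A linear model with 1 mean per group was fitted to all 13 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 9 residual and 2.28 prior degrees of freedom. Each of the 6 comparisons is a contrast tested two-sided, adjusted by Benjamini-Hochberg over all genes and called at an adjusted p under 0.05. For 32 gene lists (629 of 710 symbols measured) limma's camera with a preset correlation of 0.01 compared the members with all other genes, adjusted over 192 list tests, of which 102 were called. With the correlation estimated from the arrays camera called 0 of 192 (9 at an unadjusted p under 0.05, lowest adjusted p 0.466). The fry test, which asks whether the members move on balance one way without comparing them with other genes, called 95, of which 82 were also called by camera. For each of the 102 called lists the adjusted p with an estimated correlation was the highest over its 26 alternatives, so the ranges over alternatives end at it, and 69 were called under every other alternative.

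Lists are reported with their mean log2 difference and the number of arrays of the first group whose list mean lay beyond every array of the second. Members were counted over all genes and again adjusted over the list alone. Lists, tests, alternatives and the rule for naming genes were chosen before the data were examined. The rule names Mycn and Alk, up to 8 of the largest rises and falls per comparison among called genes of at least 2-fold whose groups do not overlap, leaving out predicted, immunoglobulin and sex-linked genes, and up to 3 called members per list by size. Control probe sets were compared between groups by two-sided exact permutation tests, which cannot go below 0.1 for 3 arrays against 3 and 0.0286 for 4 against 3. Between single groups no such test passed after Benjamini-Hochberg adjustment (lowest 0.172), and the tests of the double transgenic arrays against the other 10 were chosen after the values were seen. Sex was read from Xist and Y-linked genes, which gave 3 female adrenal arrays, 2 female and 1 male mutALK, 1 female and 3 male MYCN and 1 female and 2 male double transgenic arrays.

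The alternatives were quantile normalization again, centring of each array on its median, the mean of all probe sets of a gene, every probe set on its own, leaving out the dimmest 40% of genes, a variance trend with robust eBayes, array weights, arrays of the compared groups alone, averaging or blocking arrays that share a title number, sex as a covariate, leaving out each array and the other list tests. After the data were seen, leaving out the 5 arrays whose liver list mean was above 8 (called the liver arrays; 1 mutALK, 3 MYCN, 2 adrenal and 2 double transgenic arrays remain, so mutALK is 1 array whose spread comes from the other groups), and leaving out adrenal 2 and double transgenic 1 together, were added. On simulated data with 200 changed genes among 18193, the fit recovered 58 to 71% of changes by 1 log2 unit and 84 to 93% of those by 2, with 6 to 12 false calls. Camera recovered a list shifted by 0.5 in each comparison with 0 calls among 31 others, which does not check the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.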

Results

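Tumours of 3 transgenic mouse models of neuroblastoma, a childhood cancer of the sympathetic nervous system, were set against normal adrenal gland on mouse expression arrays. Tumours driven by mutated ALK (a receptor tyrosine kinase, here mutALK, n = 3 arrays), by MYCN (a transcription factor, n = 4) or by both (double transgenic, n = 3) and the adrenal gland (n = 3) gave 13 arrays. Values are log2 expression, with differences as first group minus second ± SE and levels as mean ± SD. The median of each array lay between 5.8 and 5.9. Correlations between arrays of one group, taken across genes, which are not independent replicates, ranged from 0.938 to 0.991. Signal over background was not analysed. Y-linked genes, absent from females, read 2.73 to 3.53 in the female arrays, so where a group lies near that level a difference may be only a lower bound. The labels do not say that each array comes from another animal, so the p-values measure the spread between these samples.

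**Figure D1:**
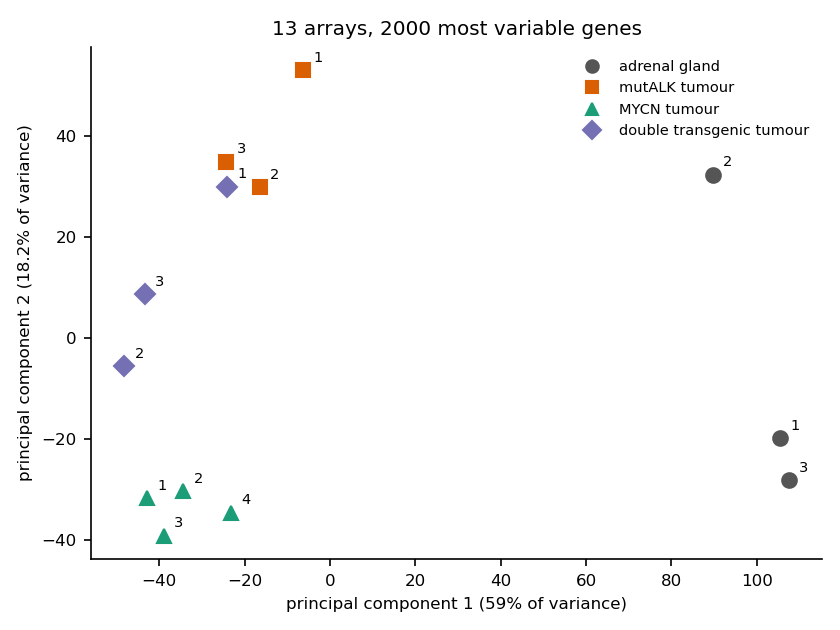
Scores of the 13 arrays on the first principal components of the 2000 most variable genes, in log2 units, with 1 point per array, its replicate number beside it and a shape and colour per group. Component 1 held 59% of the variance and parts adrenal from tumour arrays, and component 2 held 18.2%.

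Mycn, the mouse counterpart of the MYCN transgene, and Alk are the genes the models target, and their probe sets read the mouse transcripts. Whether these probe sets also read the transgenes is not given, so their levels do not check the labels. The brightest Mycn probe set was at 12.03 ± 0.33 in mutALK, 6.35 ± 0.86 in MYCN and 10.19 ± 0.64 in double transgenic tumours, against 7.69 ± 0.92 in adrenal gland. Against adrenal it rose by 4.35 ± 0.55 in mutALK (adjusted p = 7.74e-05) and rose by 2.5 ± 0.55 in double transgenic tumours (0.00249) and fell by 1.34 ± 0.51 in MYCN tumours (0.0474). Between tumours Mycn was higher in mutALK than in MYCN tumours at 5.68 ± 0.51 (adjusted p = 3.16e-05), higher in double transgenic than in MYCN tumours at 3.84 ± 0.51 (0.00141) and lower in double transgenic than in mutALK tumours at -1.85 ± 0.55 (0.0446). In MYCN minus adrenal Mycn lost its call without mutALK 1, 2 or 3, MYCN 1, 2 or 3, adrenal 1 or 2 or double transgenic 1 or 2 (value -0.83 without adrenal 1, adjusted p 0.054 to 0.218, 0.000919 to 0.396 over alternatives). In double transgenic minus mutALK Mycn lost its call without mutALK 1, 2 or 3, MYCN 1 or 3 or double transgenic 1 or 2 (adjusted p 0.058 to 0.145, 0.0305 to 0.265 over alternatives). The other Mycn probe sets differed less, with mutALK minus MYCN values of 0.07 ± 0.15 and 0.01 ± 0.11. With every probe set tested on its own the brighter of these rose against adrenal by 0.98 ± 0.16, 0.91 ± 0.15 and 0.83 ± 0.16 in mutALK, MYCN and double transgenic tumours (adjusted p = 0.000707, 0.000464 and 0.00157), so in MYCN tumours it moved against the brightest probe set, whose adjusted p in that fit was 0.0535. Alk was at 8.79 ± 0.33, 9.44 ± 0.34 and 9.11 ± 0.37 in mutALK, MYCN and double transgenic tumours against 5.17 ± 0.29 in adrenal, so that it rose by 3.62 ± 0.25, 4.28 ± 0.24 and 3.95 ± 0.25 (adjusted p = 1.45e-06, 1.46e-07 and 5.61e-07). Between tumours Alk passed no test, with mutALK minus MYCN at -0.66 ± 0.24 (adjusted p = 0.0557), double transgenic minus MYCN at -0.33 ± 0.24 (0.423) and double transgenic minus mutALK at 0.33 ± 0.25 (0.449). In mutALK minus MYCN Alk gained a call without MYCN 2, adrenal 2 or double transgenic 1 or 3 (adjusted p 0.039 to 0.0495, 0.0321 to 0.209 over alternatives).

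**Figure D2:**
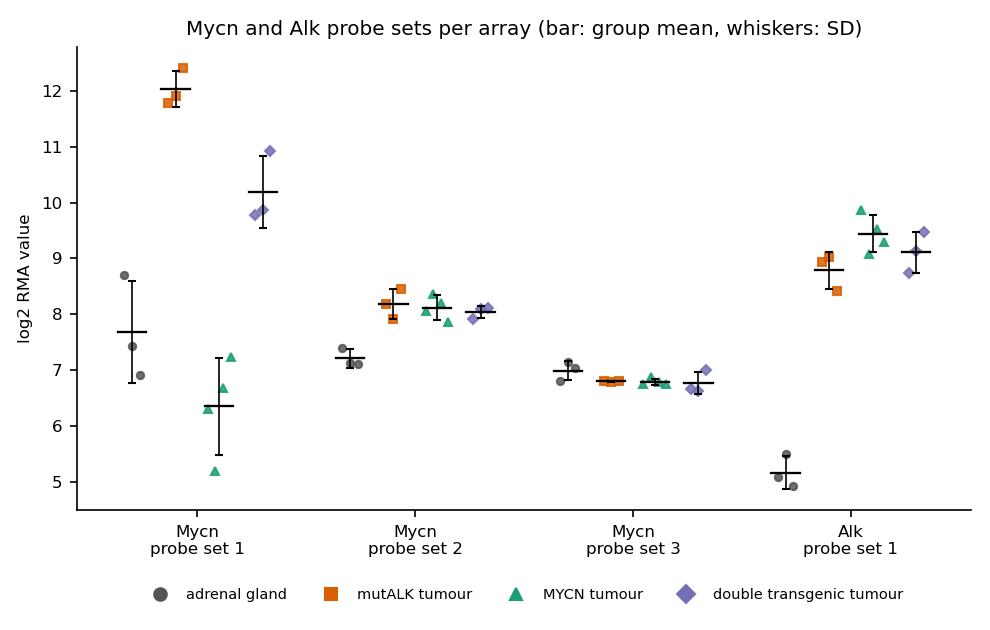
Log2 expression of the 3 Mycn probe sets and the Alk probe set in each array, by group, with bars at the group mean and whiskers of 1 SD. The brightest Mycn probe set averages 12.03 in mutALK and 6.35 in MYCN tumours, while Alk averages 8.79 to 9.44 in tumours and 5.17 in adrenal gland.

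Tumours driven by mutated ALK carried neuronal and cell division transcripts that the adrenal gland had at far lower levels, and had far lower levels of its steroid hormone transcripts. Dcx, a microtubule protein of young neurons, averaged 10.81 ± 0.48 in mutALK tumours and 3.99 ± 0.44 in adrenal gland (n = 3 against 3), and Cyp11b1, which makes corticosterone, 4.22 ± 0.14 and 13.46 ± 0.46. In this comparison 7684 of 18193 genes (42.2%) differed, 3871 higher and 3813 lower in the tumours, and 4251 of them at least 2-fold. The largest rises were Bmpr1b, a BMP receptor, at 7.31 ± 0.54, Cartpt, a neuropeptide precursor, at 7.21 ± 0.44, Pou3f3, a transcription factor of the nervous system, at 6.93 ± 0.96, Dcx at 6.83 ± 0.28, S100a8, a neutrophil protein, at 6.58 ± 0.51, Gap43, a growth cone protein, at 6.46 ± 1.31, Nxf3, of a family of RNA export factors, at 6.23 ± 0.82 and Shox2, a homeobox factor, at 6.2 ± 0.51. The largest falls were Hsd3b1, a steroid dehydrogenase, at -10.27 ± 1.14, Cyp11b1 at -9.24 ± 0.56, Cyp11a1, which starts steroid synthesis, at -9.18 ± 0.53, Hao2, a peroxisomal oxidase, at -8.91 ± 0.91, Akr1cl at -8.19 ± 0.52, Mc2r, the ACTH receptor, at -7.8 ± 0.38, Akr1c18, which breaks down progesterone, at -7.65 ± 0.65 and Thrsp, a lipid synthesis protein, at -7.53 ± 1.25. The highest adjusted p of these 16 genes was 0.00195.

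Genes of nerve cells and of the sympathetic lineage were raised and cortex genes lowered. The pan-neuronal list, genes most neurons share, was higher at a mean of 3.93 in 3 of 3 arrays (adjusted p = 6.81e-10, adjusted p = 0.542 with an estimated correlation). Of its 29 members 27 rose, 0 fell and 2 were not called (28 and 0 adjusted over the list alone), led by Dcx at 6.83 ± 0.28 and Gap43 at 6.46 ± 1.31. The sympathoadrenal transcription factor list, factors that set sympathetic and adrenal medulla identity, was higher at a mean of 2.45 in 3 of 3 arrays (adjusted p = 1.88e-05, adjusted p = 0.466 with an estimated correlation). Among its 16 members 12 rose, 0 fell and 4 were not called (12 and 0 adjusted over the list alone), with Sox11 at 5.73 ± 0.19 and Tfap2b at 4.46 ± 0.5 in front. The adrenal cortex list, enzymes and receptors of steroid making cells, was lower at a mean of -6.58 in 3 of 3 arrays (adjusted p = 1.41e-12, adjusted p = 0.466 with an estimated correlation). Its 15 members divided as 0 that rose, 15 that fell and 0 not called (0 and 15 adjusted over the list alone), and the largest values were Hsd3b1 at -10.27 ± 1.14 and Cyp11b1 at -9.24 ± 0.56. The adrenal arrays were not alike here, since adrenal 2 had a pan-neuronal mean of 9.99 against 6.73 and 5.97 and a cortex mean of 11.15 against 12.43 and 12.76. The catecholamine list, which makes and stores noradrenaline and adrenaline, was not called (adjusted p = 0.638), although 7 rose, 5 fell and 8 were not called (8 and 5 adjusted over the list alone), with Slc18a2 at 3.59 ± 0.79, Ddc at 2.62 ± 0.59 and Pcsk1 at -2.2 ± 0.28.

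Growth genes were higher. The mitosis list, genes of the spindle and of chromosome separation, was higher at a mean of 2.57 in 3 of 3 arrays (adjusted p = 5.21e-16, adjusted p = 0.466 with an estimated correlation). Of its 31 members 30 rose, 0 fell and 1 was not called (30 and 0 adjusted over the list alone), led by Ube2c at 4.26 ± 0.31 and Bub1 at 3.85 ± 0.32. The DNA replication list, genes that copy DNA, was higher at a mean of 1.58 in 3 of 3 arrays (adjusted p = 1.91e-12, adjusted p = 0.539 with an estimated correlation), with 31 members higher, 0 lower and 4 not called (33 and 0 adjusted over the list alone). The ribosome biogenesis list, nucleolar genes that assemble ribosomes, was higher at a mean of 0.39 in 3 of 3 arrays (adjusted p = 0.00517, adjusted p = 0.783 with an estimated correlation), with 14 members higher, 3 lower and 19 not called (15 and 3 adjusted over the list alone). Also higher were the MYC target and ribosomal protein lists (adjusted p 0.00154 to 0.0218, adjusted p = 0.705 with an estimated correlation). The ribosome biogenesis list lost its call without adrenal 2 (mean 0.25, adjusted p = 0.0946, 0.000393 to 0.783 over alternatives). The MYC target list lost its call without mutALK 3 or adrenal 2 (mean 0.19 without mutALK 3, adjusted p 0.0702 to 0.114, 0.0059 to 0.705 over alternatives). With mutALK 2 alone in its group (without the liver arrays) the ribosome biogenesis, MYC target and ribosomal protein means were 0.12, 0.1 and 0.1 (adjusted p 0.265 to 0.46). The ribosomal protein mean was 0.19 without adrenal 2.

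Immediate early, MHC class I and interferon lists were lower. The immediate early list, fast responders to stimulation or handling, was lower at a mean of -1.38 in 3 of 3 arrays (adjusted p = 0.000391, adjusted p = 0.466 with an estimated correlation), with 1 member higher, 10 lower and 8 not called (1 and 10 adjusted over the list alone). The MHC class I list, genes that load antigen for T cells, was lower at a mean of -1.46 in 3 of 3 arrays (adjusted p = 0.000212, adjusted p = 0.59 with an estimated correlation), with 0 members higher, 11 lower and 3 not called (0 and 12 adjusted over the list alone). The interferon list was lower at a mean of -1.43 in 3 of 3 arrays (adjusted p = 0.000616, adjusted p = 0.635 with an estimated correlation). Among its 22 members 1 rose, 14 fell and 7 were not called (1 and 14 adjusted over the list alone), with Xaf1 at -3.32 ± 0.46 and Ifit1 at -2.86 ± 0.62 in front. The interferon mean of mutALK 1 was 7.99 against 6.52 and 6.1 in the other mutALK arrays, and its MHC class I mean was 9.78 against 8.66 and 8.31.

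Vessel, macrophage and some further lists also differed. The endothelial list, genes of blood vessel lining, was lower at a mean of -1.64 in 3 of 3 arrays (adjusted p = 8.06e-07, adjusted p = 0.539 with an estimated correlation), with 0 members higher, 18 lower and 1 not called (1 and 18 adjusted over the list alone). The macrophage list was higher at a mean of 0.6 in 1 of 3 arrays (adjusted p = 0.0314, adjusted p = 0.792 with an estimated correlation), with 5 members higher, 0 lower and 14 not called (2 and 0 adjusted over the list alone). Also lower were the oxidative phosphorylation, adipocyte and pancreas acinar lists (adjusted p 4.26e-06 to 0.0211, adjusted p 0.466 to 0.648 with an estimated correlation). The fat cell mean was 12.27 in adrenal 2 against 10.98 and 10.46, and its pancreas mean was 6.95 against 5.83 and 6.01. The macrophage list lost its call without mutALK 1 or adrenal 2 (mean 0.34 without mutALK 1 and 0.35 without adrenal 2, adjusted p 0.19 to 0.217, 0.00354 to 0.792 over alternatives). The pancreas acinar list lost its call without adrenal 2 (adjusted p = 0.199, 0.000846 to 0.622 over alternatives). With mutALK 2 alone in its group (without the liver arrays) the macrophage and pancreas acinar means were 0.14 and -0.72 (adjusted p 0.421 to 0.466). The oxidative phosphorylation mean was -0.4 without adrenal 2.

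No call was made for the catecholamine, neurotrophin and GDNF receptor, neural crest progenitor, Schwann cell, cholesterol synthesis, MAPK feedback, FOXO target, p53 target, hypoxia and glycolysis, T cell, B cell, fibroblast and matrix, kidney, liver, skeletal muscle and erythroid lists (adjusted p 0.0974 to 0.894). Median, mean and test direction differed in sign for the p53 target list (-0.32, 0.1, up), the hypoxia and glycolysis list (-0.07, 0.01, down), the T cell list (0.06, -0.002, down) and the skeletal muscle list (0.02, -0.17, down). The neurotrophin and GDNF receptor list gained a call without adrenal 2 (adjusted p = 0.0137, 0.00904 to 0.771 over alternatives). In the neurotrophin and GDNF receptor list 7 members rose, 2 fell and 6 were not called (7 and 2 adjusted over the list alone), with Ret at 4.57 ± 1.08. Liver transcripts were high in 5 arrays spread over all groups, with list means of 10.76 in mutALK 1, 9.41 in mutALK 3, 8.52 in MYCN 2, 10.73 in adrenal 2 and 11.81 in double transgenic 1, against 4.34 to 5.68 in the other 8.

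MYCN tumours had cell division and ribosome assembly genes higher than the adrenal gland and steroid, vessel, interferon and MHC class I genes lower. Sox11, a transcription factor of immature neurons, averaged 11.51 ± 0.21 in the tumours and 5.01 ± 0.29 in the gland (n = 4 against 3), and Cyp11a1 3.96 ± 0.21 and 13.28 ± 0.68. Here 9128 of 18193 genes (50.2%) differed, 4612 higher and 4516 lower in the tumours, and 5211 of them at least 2-fold. At the upper end stood Sox11 at 6.5 ± 0.18, Rec114, a meiotic recombination gene, at 6.31 ± 0.18, Dcx at 6.24 ± 0.26, Fut9, a fucosyltransferase, at 6.05 ± 0.23, Cd5l, which macrophages secrete, at 6.02 ± 0.42, Nxf3 at 5.98 ± 0.77, Eya4, a transcription cofactor, at 5.95 ± 0.52 and Tox3 at 5.94 ± 0.74. At the lower end stood Hsd3b1 at -10.19 ± 1.06, Cyp11a1 at -9.32 ± 0.5, Cyp11b1 at -9.26 ± 0.52, Hao2 at -8.99 ± 0.86, Akr1cl at -8.23 ± 0.49, Akr1d1, a steroid reductase, at -7.99 ± 0.63, Mc2r at -7.76 ± 0.36 and Adh1, an alcohol dehydrogenase, at -7.7 ± 1.47. The highest adjusted p of these 16 genes was 0.00091.

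Neuronal genes were raised here too, but genes of catecholamine handling were lower than in the gland. The pan-neuronal list was higher at a mean of 2.6 in 4 of 4 arrays (adjusted p = 7.6e-05, adjusted p = 0.723 with an estimated correlation). Its 29 members divided as 20 that rose, 0 that fell and 9 not called (20 and 1 adjusted over the list alone), and the largest values were Dcx at 6.24 ± 0.26 and Nefl at 5.15 ± 1.13. The catecholamine list was lower at a mean of -1.12 in 4 of 4 arrays (adjusted p = 0.0116, adjusted p = 0.539 with an estimated correlation). Of its 20 members 3 rose, 11 fell and 6 were not called (3 and 11 adjusted over the list alone), led by Scg2 at -6.01 ± 0.45 and Slc6a2 at -3.7 ± 1.06. Scg2 is a granule protein and Slc6a2 the noradrenaline transporter, which was at -2.15 without adrenal 2 and -1.78 without the liver arrays and lost its call with the mean of all its probe sets, with sex as a covariate and without the liver arrays (adjusted p 0.073 to 0.087). Also higher was the sympathoadrenal transcription factor list (adjusted p = 0.00141, adjusted p = 0.539 with an estimated correlation). The adrenal cortex and Schwann cell lists were lower as well (adjusted p 2.51e-10 to 0.0493, adjusted p 0.466 to 0.638 with an estimated correlation). In adrenal 2 the Schwann cell mean was 8.49 against 7.1 and 6.86 in the other adrenal arrays. The Schwann cell list lost its call without mutALK 2, MYCN 1, 2 or 4, adrenal 2 or double transgenic 1, 2 or 3 (mean -0.85 without adrenal 2, adjusted p 0.0501 to 0.115, 0.0049 to 0.638 over alternatives). It also did with sex as a covariate (adjusted p = 0.0708). Without the liver arrays the catecholamine list lost its call (adjusted p = 0.0697, 0.000455 to 0.539 over alternatives).

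Every member of the mitosis list passed the test. The mitosis list was higher at a mean of 4.08 in 4 of 4 arrays (adjusted p = 1.76e-18, adjusted p = 0.466 with an estimated correlation). Among its 31 members 31 rose, 0 fell and 0 were not called (31 and 0 adjusted over the list alone), with Bub1 at 5.66 ± 0.3 and Kif2c at 5.13 ± 0.28 in front. The ribosome biogenesis list was higher at a mean of 1.5 in 4 of 4 arrays (adjusted p = 1.13e-13, adjusted p = 0.466 with an estimated correlation). Its 36 members divided as 34 that rose, 0 that fell and 2 not called (34 and 0 adjusted over the list alone), and the largest values were Rrp1b at 2.84 ± 0.18 and Nop56 at 2.66 ± 0.17. The MYC target list, metabolic and translation genes that MYC proteins are known to raise, was higher at a mean of 0.97 in 4 of 4 arrays (adjusted p = 6.47e-06, adjusted p = 0.466 with an estimated correlation). Of its 29 members 21 rose, 3 fell and 5 were not called (21 and 3 adjusted over the list alone), led by Ccnd2 at -3.87 ± 0.5, Mthfd1l at 2.62 ± 0.24 and Cad at 2.61 ± 0.2. Ccnd2, a cyclin, was among the 3 members that fell. The DNA replication and ribosomal protein lists were higher as well (adjusted p 1.61e-17 to 3.98e-06, adjusted p 0.466 to 0.542 with an estimated correlation).

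MAPK feedback, metabolic, interferon and several tissue lists were lower. The MAPK feedback list, genes that MAPK signalling switches on to restrain itself, was lower at a mean of -1.06 in 4 of 4 arrays (adjusted p = 0.0135, adjusted p = 0.622 with an estimated correlation). Among its 20 members 1 rose, 11 fell and 8 were not called (1 and 11 adjusted over the list alone), with Ier3 at -3.94 ± 0.4 and Etv5 at -3.05 ± 0.31 in front. The cholesterol synthesis list was lower at a mean of -1.19 in 4 of 4 arrays (adjusted p = 0.00022, adjusted p = 0.539 with an estimated correlation), with 1 member higher, 15 lower and 3 not called (1 and 15 adjusted over the list alone). The oxidative phosphorylation list, the mitochondrial respiratory chain, was lower at a mean of -0.53 in 4 of 4 arrays (adjusted p = 0.000286, adjusted p = 0.747 with an estimated correlation), with 0 members higher, 17 lower and 14 not called (0 and 20 adjusted over the list alone). The interferon list was lower at a mean of -2.27 in 4 of 4 arrays (adjusted p = 1.64e-05, adjusted p = 0.539 with an estimated correlation), with 0 members higher, 17 lower and 5 not called (1 and 18 adjusted over the list alone). The FOXO target, immediate early, hypoxia and glycolysis, MHC class I, endothelial, fibroblast and matrix, adipocyte and pancreas acinar lists were lower as well (adjusted p 3.98e-06 to 0.0226, adjusted p 0.466 to 0.661 with an estimated correlation). Without adrenal 2 the hypoxia and glycolysis, fibroblast and matrix and pancreas acinar lists lost their calls. Their adjusted p were 0.0854, 0.0646 and 0.106 (over alternatives 0.00821 to 0.638, 0.00271 to 0.661 and 0.000348 to 0.622). Without the liver arrays they lost them too (hypoxia and glycolysis mean -0.39, adjusted p 0.051 to 0.179). The fibroblast and matrix list also did with sex as a covariate (adjusted p = 0.0739). The oxidative phosphorylation mean was -0.28 without adrenal 2.

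No call was made for the neurotrophin and GDNF receptor, neural crest progenitor, p53 target, macrophage, T cell, B cell, kidney, liver, skeletal muscle and erythroid lists (adjusted p 0.0696 to 0.806). Median, mean and test direction differed in sign for the neurotrophin and GDNF receptor list (-0.32, 0.47, up) and the T cell list (0.004, -0.09, down). The neural crest progenitor list gained a call without adrenal 3 (adjusted p = 0.0436, 0.00256 to 0.59 over alternatives).

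Tumours with both transgenes shared the neuronal and dividing profile and had lower vessel, matrix and fat cell transcripts than the gland. Dcx averaged 11.11 ± 0.2 in double transgenic tumours and 3.99 ± 0.44 in adrenal gland (n = 3 against 3), and Adipoq, the fat cell hormone adiponectin, 4.16 ± 1.05 and 13.03 ± 0.76. Against adrenal 8835 of 18193 genes (48.6%) differed, 4428 higher and 4407 lower in the tumours, and 5109 of them at least 2-fold. Highest were Dcx at 7.12 ± 0.28, Sox11 at 6.13 ± 0.19, Creb5 at 6.02 ± 0.36, Elavl2, a neuronal RNA-binding protein, at 5.92 ± 1.38, Pou3f3 at 5.85 ± 0.96, Cartpt at 5.84 ± 0.44, Shox2 at 5.81 ± 0.51 and Nefm, a neurofilament, at 5.8 ± 1.05. Lowest were Adipoq at -8.86 ± 1.63, Hsd3b1 at -8.57 ± 1.14, Cyp11a1 at -8.52 ± 0.53, Cyp11b1 at -8.21 ± 0.56, Mrap, a partner of the ACTH receptor, at -7.84 ± 0.61, Akr1cl at -7.64 ± 0.52, Hao2 at -7.62 ± 0.91 and Mc2r at -7.3 ± 0.38. The highest adjusted p of these 16 genes was 0.00368.

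Neuronal and growth lists were higher, as in the other tumours against the gland. The pan-neuronal list was higher at a mean of 3.64 in 3 of 3 arrays (adjusted p = 1.16e-07, adjusted p = 0.622 with an estimated correlation). Its 29 members divided as 27 that rose, 0 that fell and 2 not called (28 and 0 adjusted over the list alone), and the largest values were Dcx at 7.12 ± 0.28 and Elavl2 at 5.92 ± 1.38. The mitosis list was higher at a mean of 3.69 in 3 of 3 arrays (adjusted p = 2.28e-18, adjusted p = 0.466 with an estimated correlation), with 31 members higher, 0 lower and 0 not called (31 and 0 adjusted over the list alone). Also higher were the ribosome biogenesis, sympathoadrenal transcription factor, DNA replication, MYC target and ribosomal protein lists (adjusted p 2.78e-16 to 0.000435, adjusted p 0.466 to 0.59 with an estimated correlation). The labelling spike-ins, bacterial RNAs added before labelling, averaged 6.88 ± 0.34 in the 3 double transgenic arrays and 8.8 ± 0.38 in the other 10 arrays (two-sided exact permutation p = 0.0035 over 286 splits). Dap, another such RNA, had a 3' minus 5' difference of 3.08 ± 0.19 against 1.5 ± 0.12 (0.0035), and the 18S probe sets stood at 12.23 ± 0.21 against 13.02 ± 0.19 (0.0035).

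Cortex, vessel, matrix and fat cell lists were lower. The adrenal cortex list was lower at a mean of -6.24 in 3 of 3 arrays (adjusted p = 3.37e-10, adjusted p = 0.466 with an estimated correlation), with 0 members higher, 15 lower and 0 not called (0 and 15 adjusted over the list alone). The endothelial list was lower at a mean of -2.89 in 3 of 3 arrays (adjusted p = 6.07e-10, adjusted p = 0.466 with an estimated correlation). Of its 19 members 0 rose, 18 fell and 1 was not called (0 and 18 adjusted over the list alone), led by Emcn at -5.17 ± 0.58 and Tek at -4.45 ± 0.44. The fibroblast and matrix list, collagens and other connective tissue genes, was lower at a mean of -2.24 in 3 of 3 arrays (adjusted p = 9.23e-06, adjusted p = 0.466 with an estimated correlation), with 0 members higher, 17 lower and 4 not called (0 and 17 adjusted over the list alone). The adipocyte list, fat cell genes, was lower at a mean of -5.24 in 3 of 3 arrays (adjusted p = 7.39e-06, adjusted p = 0.466 with an estimated correlation). Among its 13 members 0 rose, 13 fell and 0 were not called (0 and 13 adjusted over the list alone), with Adipoq at -8.86 ± 1.63 and Fabp4 at -7.26 ± 0.78 in front. Also lower were the interferon, MHC class I, immediate early, FOXO target, cholesterol synthesis, oxidative phosphorylation and pancreas acinar lists (adjusted p 1.02e-05 to 0.0316, adjusted p 0.466 to 0.726 with an estimated correlation). Double transgenic 1 had an adrenal cortex mean of 7.02, against 5.14 and 5.45 in the others of its group. The pancreas acinar list lost its call without adrenal 2 (adjusted p = 0.165, 0.000741 to 0.638 over alternatives) and without the liver arrays (0.205). The oxidative phosphorylation mean was -0.33 without adrenal 2.

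No call was made for the catecholamine, neurotrophin and GDNF receptor, neural crest progenitor, Schwann cell, MAPK feedback, p53 target, hypoxia and glycolysis, macrophage, T cell, B cell, kidney, liver, skeletal muscle and erythroid lists (adjusted p 0.118 to 0.934). The macrophage list gained a call without the liver arrays (adjusted p = 0.0466, 0.0466 to 0.964 over alternatives).

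The 3 tumour groups shared 2663 genes higher and 2882 genes lower than in the adrenal gland. Independent calls would share 238.8 and 229.3. Unchanged groups simulated against these adrenal arrays shared 0 in all 20 simulations, which cannot show what shared controls add to real calls. All 3 comparisons share 3 adrenal arrays, too few to be divided, so part of this excess can come from them.

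**Figure D3:**
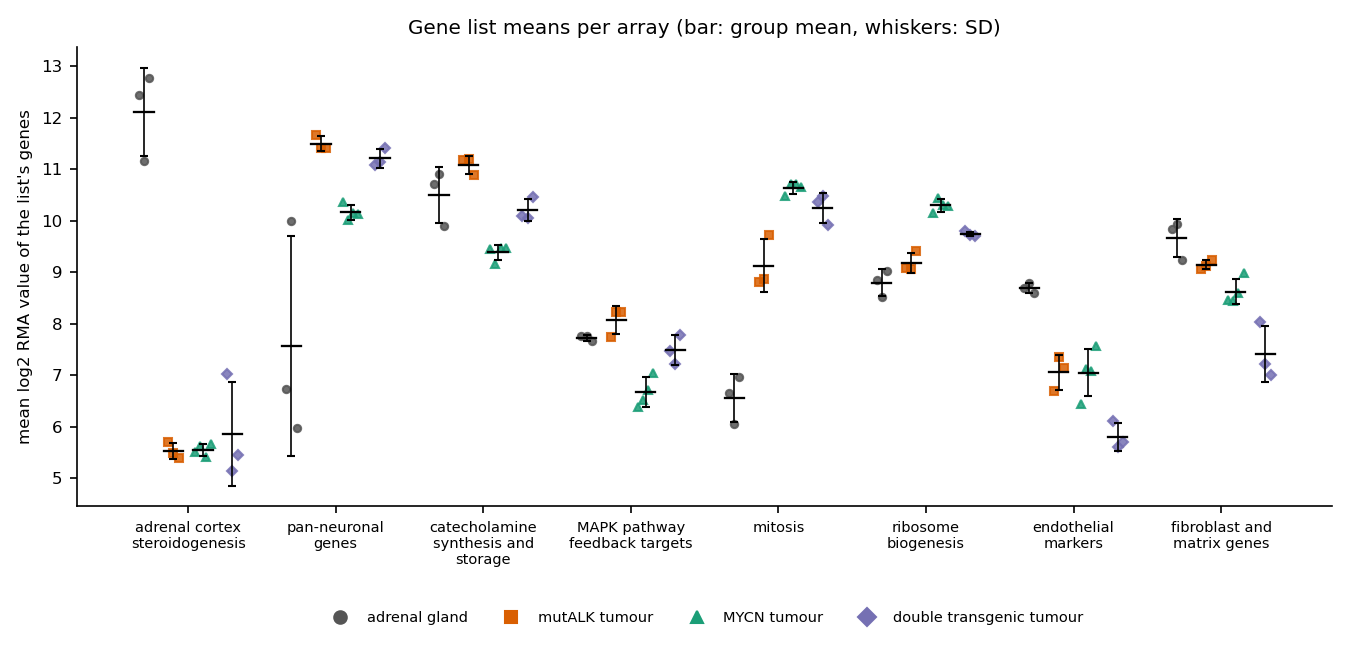
Mean log2 expression of the members of 8 gene lists in each array, by group, with bars at the group mean and whiskers of 1 SD. The adrenal cortex list averages 12.12 in adrenal gland and 5.54 to 5.87 in tumours, the mitosis list 6.56 and 9.13 to 10.64, and the endothelial list 8.7 in adrenal gland and 5.81 in double transgenic tumours.

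Between the single drivers, mutALK tumours had more catecholamine and MAPK feedback transcripts, and MYCN tumours had more of cell division and ribosome assembly. Prph, the neurofilament relative peripherin of peripheral neurons, averaged 12.79 ± 0.19 in mutALK and 4.1 ± 0.27 in MYCN tumours (n = 3 against 4), and Slc6a2, the noradrenaline transporter, 12.7 ± 0.86 and 6.37 ± 1.05. Of all genes tested, 5603 of 18193 genes (30.8%) differed, 2478 higher and 3125 lower in the mutALK tumours, and 2299 of them at least 2-fold. Higher in mutALK tumours were Prph at 8.69 ± 1.31, S100a8 at 6.87 ± 0.47, Chl1, a neural adhesion protein, at 6.65 ± 0.48, Apod, a lipid carrier, at 6.52 ± 0.73, Slc6a2 at 6.33 ± 1.06, S100a9, the partner of S100a8, at 6.24 ± 0.4, Vip, a neuropeptide, at 5.8 ± 1.16 and Chil3, of myeloid cells, at 5.69 ± 0.57. Higher in MYCN tumours were St18, a zinc finger factor, at -7.57 ± 0.68, Ppp1r17, a phosphatase inhibitor, at -5.63 ± 0.49, Hoxc8, a homeobox factor, at -5.6 ± 1.01, Dach1, a transcription factor, at -5.13 ± 0.38, Ripply2 at -5.0 ± 0.45, Gpm6a, a neuronal membrane protein, at -4.68 ± 0.82, Tox3 at -4.62 ± 0.74 and Sfrp2, a secreted Wnt-binding protein, at -4.51 ± 0.49. The highest adjusted p of these 16 genes was 0.00292.

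Genes of transmitter handling and of feedback on growth signals were higher on the mutALK side. The catecholamine list was higher at a mean of 1.7 in 3 of 3 arrays (adjusted p = 5.75e-06, adjusted p = 0.466 with an estimated correlation). Its 20 members divided as 12 that rose, 0 that fell and 8 not called (13 and 0 adjusted over the list alone), and the largest values were Slc6a2 at 6.33 ± 1.06, Scg2 at 5.43 ± 0.45 and Dbh at 3.62 ± 0.49. Dbh makes noradrenaline from dopamine. The pan-neuronal list was higher at a mean of 1.33 in 3 of 3 arrays (adjusted p = 0.00138, adjusted p = 0.783 with an estimated correlation). Of its 29 members 5 rose, 1 fell and 23 were not called (3 and 1 adjusted over the list alone), led by Prph at 8.69 ± 1.31 and Dpysl3 at 3.29 ± 0.65. SEs pool all groups, and without adrenal 2 the list's adjusted p was 4e-09 at the same mean. The MAPK feedback list was higher at a mean of 1.4 in 3 of 3 arrays (adjusted p = 1.15e-06, adjusted p = 0.466 with an estimated correlation). Among its 20 members 12 rose, 0 fell and 8 were not called (14 and 0 adjusted over the list alone), with Spry4 at 3.8 ± 0.53 and Etv5 at 3.56 ± 0.31 in front. Spry4 restrains receptor tyrosine kinase signals and Etv5 is an ETS factor that they induce. The FOXO target list, genes that FOXO factors raise when AKT is inactive, was higher at a mean of 0.78 in 3 of 3 arrays (adjusted p = 0.00213, adjusted p = 0.466 with an estimated correlation), with 8 members higher, 1 lower and 9 not called (8 and 1 adjusted over the list alone). The hypoxia and glycolysis list was higher at a mean of 0.66 in 3 of 3 arrays (adjusted p = 0.00316, adjusted p = 0.542 with an estimated correlation), with 9 members higher, 1 lower and 12 not called (10 and 1 adjusted over the list alone). Beta-actin control probe sets had a 3' minus 5' difference of 0.57 ± 0.03 in mutALK and 0.64 ± 0.04 in MYCN arrays (two-sided exact permutation p = 0.0286, adjusted p = 0.172).

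Growth lists were lower in mutALK than in MYCN tumours. The ribosome biogenesis list was lower at a mean of -1.11 in 3 of 3 arrays (adjusted p = 1.73e-18, adjusted p = 0.466 with an estimated correlation). Its 36 members divided as 0 that rose, 35 that fell and 1 not called (0 and 36 adjusted over the list alone), and the largest values were Ebna1bp2 at -2.03 ± 0.2 and Rrp1b at -1.95 ± 0.18. The MYC target list was lower at a mean of -0.67 in 3 of 3 arrays (adjusted p = 6.96e-07, adjusted p = 0.466 with an estimated correlation). Of its 29 members 0 rose, 19 fell and 10 were not called (0 and 20 adjusted over the list alone), led by Cad at -2.09 ± 0.2 and Srm at -1.73 ± 0.14. The mitosis list was lower at a mean of -1.51 in 3 of 3 arrays (adjusted p = 7.16e-14, adjusted p = 0.483 with an estimated correlation), with 0 members higher, 29 lower and 2 not called (0 and 30 adjusted over the list alone). The DNA replication and ribosomal protein lists were lower as well (adjusted p 1.11e-14 to 0.00243, adjusted p 0.482 to 0.723 with an estimated correlation).

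Interferon, red cell, Schwann cell, macrophage, matrix and cholesterol lists were also higher in mutALK tumours. The interferon list was higher at a mean of 0.83 in 2 of 3 arrays (adjusted p = 0.00248, adjusted p = 0.675 with an estimated correlation), with 4 members higher, 0 lower and 18 not called (3 and 0 adjusted over the list alone). The erythroid list, red cell genes, was higher at a mean of 1.17 in 2 of 3 arrays (adjusted p = 0.0493, adjusted p = 0.687 with an estimated correlation), with 2 members higher, 0 lower and 9 not called (2 and 0 adjusted over the list alone). The Schwann cell, macrophage, fibroblast and matrix and cholesterol synthesis lists were higher as well (adjusted p 1.29e-05 to 0.0493, adjusted p 0.466 to 0.82 with an estimated correlation). The interferon list lost its call without mutALK 1 (mean 0.27, adjusted p = 0.186, 5.37e-05 to 0.675 over alternatives). The erythroid list lost its call without mutALK 2, MYCN 1, 2 or 3, adrenal 1, 2 or 3 or double transgenic 1, 2 or 3 (mean 0.5 without mutALK 2, adjusted p 0.0539 to 0.0928, 2.66e-05 to 0.687 over alternatives). The Schwann cell list lost its call without mutALK 1 or MYCN 1 (adjusted p 0.054 to 0.0832, 0.00318 to 0.622 over alternatives). The macrophage list lost its call without mutALK 1, MYCN 1 or 2, adrenal 2 or 3 or double transgenic 1 or 2 (mean 0.22 without mutALK 1, adjusted p 0.0503 to 0.325, 0.00986 to 0.82 over alternatives). The fibroblast and matrix list lost its call without mutALK 3 (adjusted p = 0.0603, 0.0077 to 0.675 over alternatives). The Schwann cell, macrophage, fibroblast and matrix and erythroid lists lost their calls with sex as a covariate (adjusted p 0.0511 to 0.173). With mutALK 2 alone in its group (without the liver arrays) the interferon and macrophage means were 0.46 and 0.28 (adjusted p 0.117 to 0.351).

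The tests made no call for the sympathoadrenal transcription factor, neurotrophin and GDNF receptor, neural crest progenitor, adrenal cortex, immediate early, p53 target, oxidative phosphorylation, MHC class I, T cell, B cell, endothelial, adipocyte, kidney, liver, skeletal muscle and pancreas acinar lists (adjusted p 0.0539 to 0.968). Median, mean and test direction differed in sign for the immediate early list (-0.05, 0.11, down) and the endothelial list (-0.19, 0.01, down). The p53 target list gained a call without MYCN 1 or 3 or adrenal 3 (adjusted p 0.0221 to 0.0487, 0.00403 to 0.466 over alternatives). The liver list gained a call without mutALK 2 or MYCN 2 (adjusted p 0.00294 to 0.0255, 0.00294 to 0.853 over alternatives). The MHC class I list gained one without mutALK 3 and skeletal muscle without MYCN 2 (adjusted p = 0.0391 and 0.0383, up to 0.947 and 0.879 over alternatives). The p53 target and adipocyte lists gained calls with sex as a covariate (adjusted p 0.0349 to 0.0448).

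Against MYCN, double transgenic arrays had more catecholamine and MAPK feedback and fewer ribosome assembly, vessel and matrix transcripts. Prph averaged 10.87 ± 1.08 in double transgenic and 4.1 ± 0.27 in MYCN tumours (n = 3 against 4), and Egln3, a prolyl hydroxylase of the oxygen sensing pathway, 11.08 ± 0.93 and 5.72 ± 0.98. In total 2333 of 18193 genes (12.8%) differed, 1121 higher and 1212 lower in the double transgenic tumours, and 784 of them at least 2-fold. The genes that rose most were Prph at 6.76 ± 1.31, Vip at 5.58 ± 1.16, Egln3 at 5.35 ± 0.56, Edil3, a matrix protein, at 5.29 ± 0.6, Cacng5, a channel subunit, at 5.06 ± 0.62, Pgm5 at 5.0 ± 0.64, Tcf24 at 4.71 ± 0.62 and Ly6h at 4.42 ± 0.4. Those that fell most were Dach1 at -5.11 ± 0.38, Fabp4, a fat cell lipid carrier, at -4.86 ± 0.73, St18 at -4.45 ± 0.68, Morc1, a germ cell gene, at -4.14 ± 0.52, Mbnl3, a splicing factor, at -4.1 ± 0.61, Peg10, an imprinted gene, at -3.95 ± 0.49, Gpat2 at -3.93 ± 0.83 and Esm1, of vessel lining cells, at -3.81 ± 0.75. The highest adjusted p of these 16 genes was 0.0115. The count was 1249 without MYCN 2, 1467 without MYCN 3, 1494 without MYCN 4, 1368 without double transgenic 2 and 1226 without double transgenic 3. Vip lost its call without double transgenic 3 (adjusted p = 0.0555, 0.00363 to 0.0555 over alternatives).

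Catecholamine, pan-neuronal and MAPK feedback lists were higher. The catecholamine list was higher at a mean of 0.82 in 3 of 3 arrays (adjusted p = 0.00102, adjusted p = 0.466 with an estimated correlation). Among its 20 members 5 rose, 2 fell and 13 were not called (10 and 2 adjusted over the list alone), with Scg2 at 3.14 ± 0.45 and Dbh at 1.87 ± 0.49 in front. The pan-neuronal list was higher at a mean of 1.04 in 3 of 3 arrays (adjusted p = 0.000293, adjusted p = 0.752 with an estimated correlation). Its 29 members divided as 4 that rose, 0 that fell and 25 not called (4 and 0 adjusted over the list alone), led by Prph at 6.76 ± 1.31. Without adrenal 2 the list's adjusted p was 2.61e-11. The MAPK feedback list was higher at a mean of 0.82 in 3 of 3 arrays (adjusted p = 0.000576, adjusted p = 0.539 with an estimated correlation). Of its 20 members 8 rose, 3 fell and 9 were not called (8 and 3 adjusted over the list alone), led by Etv5 at 4.09 ± 0.31 and Dusp4 at 2.67 ± 0.61. The hypoxia and glycolysis and cholesterol synthesis lists were higher as well (adjusted p 0.000777 to 0.0337, adjusted p 0.539 to 0.674 with an estimated correlation). In the 3 double transgenic arrays the labelling spike-ins averaged 6.88 ± 0.34, against 8.72 ± 0.14 in MYCN arrays, and the 3' minus 5' differences of Gapdh and beta-actin were 0.58 ± 0.17 and 0.85 ± 0.19 against 0.23 ± 0.08 and 0.64 ± 0.04 (two-sided exact permutation p = 0.0286 for each, adjusted p = 0.172). The hypoxia and glycolysis list lost its call without MYCN 2, adrenal 2 or double transgenic 1 or 3 (adjusted p 0.0511 to 0.0915, 0.00572 to 0.674 over alternatives). It also did without the liver arrays (mean 0.27, adjusted p = 0.306). Dbh lost its call without MYCN 2, 3 or 4 or double transgenic 2 or 3 (adjusted p 0.0592 to 0.122, 0.0099 to 0.122 over alternatives). Dusp4 lost its call without double transgenic 3 (adjusted p = 0.0766, 0.0108 to 0.0766 over alternatives).

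Ribosome assembly genes were lower with both transgenes than with MYCN alone. Ribosome biogenesis genes, taken as a list, were lower at a mean of -0.55 in 3 of 3 arrays (adjusted p = 8.36e-13, adjusted p = 0.466 with an estimated correlation). Among its 36 members 0 rose, 19 fell and 17 were not called (0 and 25 adjusted over the list alone), with Ebna1bp2 at -1.11 ± 0.2 and Tcof1 at -0.98 ± 0.11 in front. With the mean of all its probe sets Ebna1bp2 was at 0.075 (adjusted p = 0.722, 0.00118 to 0.722 over alternatives). The MYC target list was lower at a mean of -0.38 in 3 of 3 arrays (adjusted p = 0.000202, adjusted p = 0.539 with an estimated correlation), with 0 members higher, 5 lower and 24 not called (0 and 7 adjusted over the list alone). The mitosis and DNA replication lists were lower as well (adjusted p 0.000282 to 0.00454, adjusted p 0.747 to 0.812 with an estimated correlation). The mitosis list lost its call without double transgenic 3 (mean -0.22, adjusted p = 0.245, 7.95e-05 to 0.812 over alternatives).

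Vessel and matrix genes were lower in the double transgenic tumours. The endothelial list was lower at a mean of -1.24 in 3 of 3 arrays (adjusted p = 3.71e-10, adjusted p = 0.466 with an estimated correlation). Its 19 members divided as 0 that rose, 13 that fell and 6 not called (0 and 16 adjusted over the list alone), and the largest values were Emcn at -2.42 ± 0.54 and Pecam1 at -2.27 ± 0.32. The fibroblast and matrix list was lower at a mean of -1.2 in 3 of 3 arrays (adjusted p = 3.96e-06, adjusted p = 0.466 with an estimated correlation). Of its 21 members 0 rose, 10 fell and 11 were not called (0 and 10 adjusted over the list alone), led by Acta2 at -3.38 ± 0.6 and Tagln at -2.62 ± 0.44. The macrophage list was lower at a mean of -0.52 in 2 of 3 arrays (adjusted p = 0.0173, adjusted p = 0.777 with an estimated correlation), with 0 members higher, 0 lower and 19 not called (0 and 0 adjusted over the list alone). The adipocyte and MHC class I lists were lower as well (adjusted p 0.00261 to 0.04, adjusted p 0.612 to 0.783 with an estimated correlation). The 18S probe sets were at 12.23 ± 0.21 in these arrays and 12.87 ± 0.14 in MYCN arrays, a difference of -0.64, and the labelling spike-ins differed by -1.85. The macrophage list lost its call without MYCN 4 or double transgenic 3 (mean -0.32 without double transgenic 3, adjusted p 0.0679 to 0.299, 0.000907 to 0.777 over alternatives). The MHC class I list lost its call without MYCN 1 or 4, adrenal 2 or double transgenic 3 (adjusted p 0.0718 to 0.244, 0.00115 to 0.783 over alternatives). Emcn lost its call without double transgenic 2 or 3 (adjusted p 0.0555 to 0.0619, 0.00367 to 0.0619 over alternatives).

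Not called were the sympathoadrenal transcription factor, neurotrophin and GDNF receptor, neural crest progenitor, Schwann cell, adrenal cortex, ribosomal protein, immediate early, FOXO target, p53 target, oxidative phosphorylation, interferon, T cell, B cell, kidney, liver, skeletal muscle, pancreas acinar and erythroid lists (adjusted p 0.0556 to 0.934). Median, mean and test direction differed in sign for the neurotrophin and GDNF receptor list (-0.08, 0.33, up), the neural crest progenitor list (0.06, -0.01, up) and the kidney list (-0.01, 0.03, up). The sympathoadrenal transcription factor list gained a call without MYCN 1 or 3, adrenal 2 or 3 or double transgenic 3 (adjusted p 0.0206 to 0.0458, 0.0206 to 0.696 over alternatives). The FOXO target list gained a call without MYCN 1 or 4 or double transgenic 3 (adjusted p 0.0193 to 0.0325, 0.0193 to 0.559 over alternatives). The B cell list gained a call without double transgenic 2 (adjusted p = 0.0309, 0.0309 to 0.925 over alternatives). The liver list gained a call without MYCN 2 or double transgenic 2 or 3 (adjusted p 0.0279 to 0.0315, 0.0279 to 0.897 over alternatives). Without MYCN 3, whose skeletal muscle mean was 8.02 against 5.01 to 5.12, the mean of that list turned from -0.11 to 0.62 (adjusted p = 0.0166, against 0.0166 to 0.995 over alternatives).

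Against mutALK, double transgenic arrays had more cell division and ribosome assembly and fewer vessel and matrix transcripts. S100a8 averaged 4.95 ± 0.95 in double transgenic and 11.44 ± 0.62 in mutALK tumours (n = 3 against 3), and Gpm6a 10.21 ± 0.27 and 5.11 ± 2.25. Between these groups 2624 of 18193 genes (14.4%) differed, 1526 higher and 1098 lower in the double transgenic tumours, and 954 of them at least 2-fold. Rises were largest for Gpm6a at 5.1 ± 0.88, St6gal2, a sialyltransferase, at 4.06 ± 0.55, Fras1, a basement membrane protein, at 3.97 ± 0.38, Slc35d3 at 3.96 ± 0.8, Sfrp2 at 3.86 ± 0.52, Hoxd3os1, a non-coding RNA, at 3.85 ± 0.82, Neurod6, a neuronal factor, at 3.77 ± 0.4 and Ppp1r17 at 3.63 ± 0.52. Falls were largest for S100a8 at -6.49 ± 0.51, S100a9 at -6.14 ± 0.42, Chil3 at -5.92 ± 0.61, Lcn2, a neutrophil granule protein, at -4.69 ± 0.67, Car2, a carbonic anhydrase, at -4.64 ± 0.46, Fabp4 at -4.4 ± 0.78, Slc4a1, the red cell anion exchanger, at -4.13 ± 0.96 and Itga1, an integrin, at -4.02 ± 0.3. The highest adjusted p of these 16 genes was 0.018. The count was 1497 without mutALK 1, 1145 without mutALK 2 and 1006 without double transgenic 2. Without double transgenic 2 Hoxd3os1 and Slc4a1 lost their calls (adjusted p 0.0584 and 0.0613, 0.00987 to 0.094 and 0.00244 to 0.0893 over alternatives).

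Growth lists were higher with both transgenes than with mutated ALK alone. The mitosis list was higher at a mean of 1.13 in 3 of 3 arrays (adjusted p = 4.55e-15, adjusted p = 0.466 with an estimated correlation). Among its 31 members 21 rose, 0 fell and 10 were not called (29 and 0 adjusted over the list alone), with Plk1 at 1.47 ± 0.24 and Cenpa at 1.47 ± 0.26 in front. The ribosome biogenesis list was higher at a mean of 0.55 in 3 of 3 arrays (adjusted p = 6.81e-12, adjusted p = 0.481 with an estimated correlation). Its 36 members divided as 15 that rose, 0 that fell and 21 not called (23 and 0 adjusted over the list alone), and the largest values were Rrp1b at 1.48 ± 0.19 and Ppan at 1.27 ± 0.15. Also higher were the DNA replication, MYC target and ribosomal protein lists (adjusted p 2.87e-14 to 0.00502, adjusted p 0.483 to 0.747 with an estimated correlation). The labelling spike-ins differed between these groups by -1.92, the 18S probe sets by -0.8 and the 3' minus 5' differences of Gapdh and beta-actin by 0.38 and 0.29 (two-sided exact permutation p = 0.1 for each, adjusted p = 0.2).

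Catecholamine and MAPK feedback lists were lower. The catecholamine list was lower at a mean of -0.88 in 3 of 3 arrays (adjusted p = 0.000705, adjusted p = 0.466 with an estimated correlation). Of its 20 members 0 rose, 3 fell and 17 were not called (0 and 6 adjusted over the list alone), led by Scg2 at -2.29 ± 0.48 and Chgb at -1.95 ± 0.39. The MAPK feedback list was lower at a mean of -0.58 in 2 of 3 arrays (adjusted p = 0.000905, adjusted p = 0.539 with an estimated correlation). Among its 20 members 0 rose, 4 fell and 16 were not called (0 and 5 adjusted over the list alone), with Spry4 at -2.62 ± 0.56 and Dusp6 at -2.24 ± 0.44 in front. The p53 target list, genes raised after DNA damage, was lower at a mean of -0.48 in 3 of 3 arrays (adjusted p = 0.0316, adjusted p = 0.466 with an estimated correlation), with 1 member higher, 2 lower and 15 not called (1 and 2 adjusted over the list alone). Also lower were the FOXO target and cholesterol synthesis lists (adjusted p 0.00621 to 0.0129, adjusted p 0.466 to 0.622 with an estimated correlation). The p53 target list lost its call without mutALK 1 or double transgenic 3 (adjusted p 0.067 to 0.128, 0.00914 to 0.466 over alternatives). The FOXO target list lost its call without double transgenic 3 (adjusted p = 0.0605, 0.0013 to 0.466 over alternatives). The cholesterol synthesis list lost its call without mutALK 3 or double transgenic 2 (mean -0.24 without double transgenic 2, adjusted p 0.0555 to 0.0967, 0.00045 to 0.622 over alternatives). Scg2 lost its call without mutALK 2 or double transgenic 2 (adjusted p 0.0526 to 0.0559, 0.00772 to 0.0559 over alternatives). Spry4 lost its call without double transgenic 2 (adjusted p = 0.0593, 0.0052 to 0.172 over alternatives).

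Vessel, matrix, macrophage and interferon lists were lower in the double transgenic tumours. The endothelial list was lower at a mean of -1.25 in 3 of 3 arrays (adjusted p = 3.21e-10, adjusted p = 0.466 with an estimated correlation). Its 19 members divided as 0 that rose, 13 that fell and 6 not called (0 and 16 adjusted over the list alone), and the largest values were Emcn at -2.29 ± 0.58 and Vwf at -2.2 ± 0.52. The fibroblast and matrix list was lower at a mean of -1.73 in 3 of 3 arrays (adjusted p = 1.76e-12, adjusted p = 0.466 with an estimated correlation), with 0 members higher, 15 lower and 6 not called (0 and 19 adjusted over the list alone). The macrophage list was lower at a mean of -1.0 in 3 of 3 arrays (adjusted p = 5.21e-06, adjusted p = 0.539 with an estimated correlation). Of its 19 members 0 rose, 7 fell and 12 were not called (0 and 13 adjusted over the list alone), led by Mrc1 at -2.02 ± 0.41. Also lower were the interferon, MHC class I and erythroid lists (adjusted p 8.41e-05 to 0.00962, adjusted p 0.59 to 0.648 with an estimated correlation). The labelling spike-ins differed by -1.92. The MHC class I list lost its call without mutALK 1 (mean -0.24, adjusted p = 0.104, 3.56e-05 to 0.648 over alternatives). The erythroid list lost its call without double transgenic 1 (adjusted p = 0.051, 4.13e-06 to 0.59 over alternatives). The interferon mean was -0.41 without mutALK 1. The erythroid mean was -0.7 without mutALK 2. Emcn lost its call without mutALK 2 or double transgenic 2 or 3 (adjusted p 0.0563 to 0.0997, 0.0109 to 0.0997 over alternatives). Vwf lost its call without mutALK 2 or double transgenic 2 (adjusted p 0.0741 to 0.0757, 0.0026 to 0.0757 over alternatives).

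**Figure D4:**
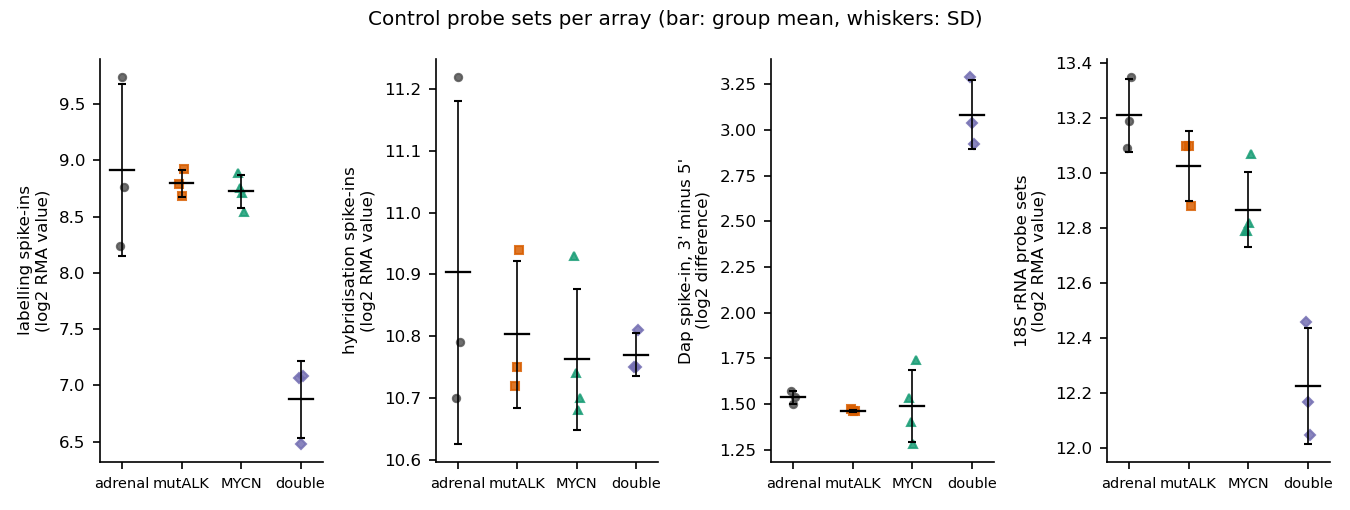
Log2 values of control probe sets in each array, by group, with bars at the group mean and whiskers of 1 SD. Labelling spike-ins average 6.88 in double transgenic arrays and 8.8 in the other 10, while hybridisation spike-ins average 10.77 and 10.82.

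Tests gave no call for the sympathoadrenal transcription factor, pan-neuronal, neurotrophin and GDNF receptor, neural crest progenitor, Schwann cell, adrenal cortex, immediate early, hypoxia and glycolysis, oxidative phosphorylation, T cell, B cell, adipocyte, kidney, liver, skeletal muscle and pancreas acinar lists (adjusted p 0.103 to 0.934). Median, mean and test direction differed in sign for the sympathoadrenal transcription factor list (-0.03, 0.03, up), the neurotrophin and GDNF receptor list (-0.04, -0.05, up) and the pancreas acinar list (0.01, -0.01, up). The hypoxia and glycolysis list gained a call without mutALK 1 (adjusted p = 0.0374, 0.0374 to 0.783 over alternatives). The liver list gained a call without mutALK 2 or double transgenic 1 (adjusted p 0.0128 to 0.0216, 0.00563 to 0.99 over alternatives). The skeletal muscle list gained a call without MYCN 3 or double transgenic 2 or 3 (adjusted p 0.00544 to 0.0491, 0.00544 to 0.853 over alternatives).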

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

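All tests of explanations in this part were chosen only after the result was seen, as were the splits of the arrays.

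In the 4 MYCN arrays 152 results (32 list means, 6 control measures and 114 genes) were checked for an array far from the other 3, and 8 were found where chance gives 7.6, about 1 in 20. The gap to the nearest array, as a share of the whole range, was 0.932 for the catecholamine mean of MYCN 2 (9.16 against 9.45 to 9.47) and 0.964 for its Ddc (12.43 against 12.6 to 12.61). It was 0.964 for the skeletal muscle mean of MYCN 3 (8.02 against 5.01 to 5.12), 0.893 for the 18S mean of MYCN 4 (13.07 against 12.79 to 12.82) and 0.933 for Xist in MYCN 4, the female of the group (13.06 against 5.24 to 5.76). In MYCN 1 it was 0.982 for Slc17a6 (9.9 against 3.21 to 3.33), 0.884 for Spry4 (3.81 against 5.56 to 5.79) and 0.869 for Stmn2 (12.81 against 11.73 to 11.87).

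The means of some lists stood above the adrenal gland in one tumour group and below it in another. Most of these sides were not called, among them every mutALK one except macrophage, and camera tested only the difference between the tumour groups (adjusted p in parentheses). Between mutALK and MYCN tumours the mean difference was 1.70 for catecholamine (5.75e-06), 1.4 for MAPK feedback (1.15e-06), 0.656 for hypoxia and glycolysis (0.00316) and 1.165 for erythroid genes (0.0493), which was 0.501 without mutALK 2 and lost its call without each of 10 arrays. In double transgenic minus MYCN tumours it was -0.515 for macrophage genes (0.0173, and -0.319 without double transgenic 3, 0.299). In double transgenic minus mutALK tumours it was -0.876 for catecholamine (0.000705), -0.578 for MAPK feedback (0.000905), -0.479 for p53 targets (0.0316), -1.002 for macrophage (5.21e-06) and -1.368 for erythroid genes (0.00962, and -0.704 without mutALK 2). With an estimated correlation these ranged from 0.466 to 0.777.

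Of 9160 probe sets without a gene name, tested apart from the genes, 1141 were called in mutALK, 1644 in MYCN and 1999 in double transgenic tumours against adrenal gland. Between tumours 627 were called in mutALK minus MYCN, 269 in double transgenic minus MYCN and 526 in double transgenic minus mutALK.

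Counts of changed genes were set against all other splits of the same arrays into groups of the same sizes, where only the real split (1 of 35) reached the real count in MYCN minus adrenal (9128, highest other 5040), mutALK minus MYCN (5603, 1449) and double transgenic minus MYCN (2333, 523), a share of 0.0286. That share is the smallest that 35 splits can give and was not adjusted for the number of comparisons. It speaks against a chance split only if the arrays are independent, which the labels do not say. For 3 arrays against 3 the 10 splits are too few for a share under 0.05, with 7684 (highest other 6) in mutALK minus adrenal, 8835 (0) in double transgenic minus adrenal and 2624 (3) in double transgenic minus mutALK.

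Adrenal 2 carried neuronal transcripts that the other adrenal arrays had at low levels. More adrenal medulla in the piece is argued against, since 0 of 10 medulla markers stood at least 1 log2 unit above both other arrays (Chgb 12.59 against 14.06 and 13.48), and so is RNA from the tumours, with 0 of 9 tumour markers (Dcx 4.49 against 3.79 and 3.68). Sympathetic ganglion tissue stays open, with 14 of 19 markers raised (median excess 2.71, range -1.91 to 6.58). Prph, Gap43, Nefm, Nefl and Stmn2 among them belong to the neuronal result itself, so the count cannot decide. Chrnb4, Ntng1, Gata3, Vip and Cartpt were not raised, and tumours express most of the 19 too. No cause beyond tissue source was tested.

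Endothelial and matrix lists were lower in double transgenic than in MYCN tumours (adjusted p = 0.466 with an estimated correlation for both). The macrophage list was lower less firmly, with 0 of 19 members called, an adjusted p of 0.777 with an estimated correlation and no call without MYCN 4 or double transgenic 3. Labelling spike-ins of the 3 double transgenic arrays differed by -1.93 from the other 10, so separate labelling cannot be told apart from the group. A lower share of all non-tumour cells alike stays open, since matrix and endothelial lists fell alike (-1.2 and -1.24). Endothelial minus macrophage list means were -2.2 ± 0.26 in double transgenic and -1.47 ± 0.15 in MYCN arrays (difference -0.73, two-sided exact permutation p = 0.0286 over 35 assignments, the smallest possible). Against mutALK arrays the same difference was -0.25 (exact p = 0.7). An effect of the added mutated ALK stays open and untested.

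The brightest Mycn probe set was far higher in mutALK than in MYCN tumours. Signal of 1 probe set, not the whole transcript, stays open. The others differed by at most 0.07, but the dimmer passed no test and may be unresponsive. Silencing of the mouse gene by the MYCN transgene as the whole cause is argued against, since double transgenic tumours, which carry it too, stood 3.84 above MYCN tumours. Whether the brightest reads part of a transgene stays open.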

How the results depend on the processing

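Leaving out the liver arrays, and adrenal 2 and double transgenic 1 together, were chosen after seeing the data, and every other alternative was planned. No paired analysis was possible because the replicate numbers only name the arrays. Title numbers are shared by mutALK 2 and 3 and by MYCN 2 and 3. By Xist and Y-linked genes mutALK 2 is female and mutALK 3 male, so these 2 are not 1 animal, and what the number stands for is not given. Every probe set on its own and arrays of the compared groups alone gave no list tests.

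The counts against adrenal gland, of mutALK minus MYCN and of the shared calls stayed within 1.5 times their value under every alternative. In double transgenic minus MYCN the count of 2333 became 3533 with every probe set on its own, where more features are tested, 3850 with array weights, which gave adrenal 2 a weight of 0.182, and 1394 with arrays sharing a title number averaged. In double transgenic minus mutALK the count of 2624 became 1162 with the 2 groups alone, where fewer arrays give the spread, 1624 with the averages and 1582 with the shared title number as a random block (4 arrays share a number, 11 blocks, correlation 0.456). For the weights, averages and block the cause was not tested. Of the list tests camera with an estimated correlation called 0 of 192 against 102, while fry called 95. Without single arrays the counts ranged from 6880 to 7791 (mutALK minus adrenal), 8379 to 9141 (MYCN minus adrenal), 7793 to 8806 (double transgenic minus adrenal), 4264 to 6540 (mutALK minus MYCN), 1226 without double transgenic 3 to 3369 without adrenal 2 (double transgenic minus MYCN), 1006 without double transgenic 2 to 3659 without adrenal 2 (double transgenic minus mutALK), 4939 to 5698 (shared calls) and 91 to 105 (list tests). In double transgenic minus MYCN the count was also 1249, 1467 and 1494 without MYCN 2, 3 and 4 and 1368 without double transgenic 2, and in double transgenic minus mutALK 1497 and 1145 without mutALK 1 and 2.

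Without the liver arrays the counts, in the order above, were 6175, 8611, 8419, 4379, 1982 and 1800, the shared calls 4544 and the called lists 88. All of these but 8611, 8419 and 1982 rest on mutALK 2 as the only mutALK array, so their changes cannot be put down to the liver transcripts. Without adrenal 2 and double transgenic 1 they were 7783, 9039, 8509, 6542, 3056 and 2903, with 5612 and 93.

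With the mean of all probe sets of a gene Xaf1 in mutALK minus MYCN turned from 1.45 to -0.358 (adjusted p = 0.399, 0.00326 to 0.399 over alternatives) and Ebna1bp2 in double transgenic minus MYCN from -1.11 to 0.075 (0.722, 0.00118 to 0.722), since other probe sets of these genes enter the mean. The skeletal muscle list in double transgenic minus MYCN turned from -0.114 to 0.624 without MYCN 3 (adjusted p = 0.0166), which alone had muscle transcripts in its group, and was -0.775 without double transgenic 1. Over 26 alternatives the 574 gene values kept their call or their lack of one in 14012 cases, lost the call in 734, gained it in 64 and reversed in 2, and the 192 list values kept it in 4683, lost the call in 249, gained it in 59 and reversed in 1. List calls lost were 6 with sex as a covariate, 17 without the liver arrays (11 of them where mutALK 2 stands alone), 15 without the dimmest 40% of genes, 9 with array weights, 13 without adrenal 2 and double transgenic 1, 20 with fry and 0 to 3 with each of the other alternatives that keep all arrays and the preset correlation, and the cause was not tested. With the 2 groups alone calls were lost by Ddc and Ret (mutALK minus adrenal), Mycn (MYCN minus adrenal) and Xaf1 (mutALK minus MYCN), among others. So did Slc4a1, Cenpa, Dusp6 and Tagln in double transgenic minus mutALK lose theirs (all 0.0505 to 0.0967). Signal over background was not analysed, so dim probe sets were checked only by leaving out the dimmest 40% of genes (counts within 1.5 times).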

Other observations

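Genes here were chosen after their values were seen, and no explanation was tested.

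Hoxb9, a homeobox gene, was lower in every tumour group than in the adrenal gland, at -5.42 ± 0.26 in mutALK, -5.62 ± 0.24 in MYCN and -5.48 ± 0.26 in double transgenic tumours (limma adjusted p = 2.22e-07, 4.2e-08 and 1.25e-07). Hoxc8 averaged 4.4 ± 0.97 in mutALK, 10.0 ± 0.29 in MYCN and 9.82 ± 0.4 in adrenal arrays, and stood at 8.58, 9.12 and 3.81 in double transgenic arrays 1, 2 and 3.

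Some transcripts known from neutrophils were high in the mutALK tumours, with no list of such genes tested. Beside S100a8, S100a9, Lcn2 and Chil3, Ngp was higher than in MYCN tumours at 3.51 ± 0.63 (limma adjusted p = 0.00159). So were Ltf at 2.0 ± 0.41 (0.00353), Camp at 1.95 ± 0.58 (0.0251) and Mpo at 1.14 ± 0.37 (0.0355). Elane passed no test at 0.19 ± 0.18 (0.492). Ngp, Ltf, Camp and Mpo were each highest in mutALK 2, with Ngp at 10.33 there against 6.92 and 7.6 in mutALK 1 and 3.

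Control probe sets of Gapdh had a 3' minus 5' difference of 0.58 ± 0.17 in the double transgenic and 0.24 ± 0.12 in the other 10 arrays (two-sided exact permutation p = 0.00699), while the hybridisation spike-ins passed no such test (0.682). Those of beta-actin did not pass either (0.5), where adrenal 2 stood at 1.46, although they were higher in double transgenic than in every mutALK or MYCN array.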
